A study of Homo sapiens with 2 samples.

How the data were processed

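Small RNA libraries were made from 3 µg of total RNA with a ligation-based small RNA kit, and fragments of 140 to 160 bp were taken from a gel, per the labels' protocols. There were 2 libraries, 1 of parental UM-SCC6 and 1 of UM-SCC6-M. The authors deposited 1 table with 1213 entries, of which 1178 carry miRNA names and 35 are candidate miRNAs without a database name. The submitters' processing notes name Bowtie, an aligner, without a version. The genome build, the miRNA database release, the counting and the tool behind the scaling were not given in the sources used here.

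The table has 1 column per library, holding a read signal scaled by the authors to make the libraries comparable. These deposited signal values are called normalized reads here. The scaling method is not named, and was examined from the values. Every value above 0 was a whole multiple of 1 step per library, with a largest deviation of 7.2e-05 reads. The step, taken as the worth of 1 read, was 0.119 in the UM-SCC6-M column and 0.133 in the parental column. The smallest listed values were of 9 and 8 reads, and values below 1 were listed as 0. The columns sum to 919341 and 1087359, so they are not shares of a common total. The log2 fold change column is UM-SCC6-M over parental per the file headers, and equalled the log2 of the 2 columns within 4.98e-05 where both were above 0. Where 1 column was listed as 0, the deposited log2 fold change gave that library's reads, which were whole within 0.00023 reads. The p-value and q-value columns and a mark for selected miRNAs are the authors' own comparison of the 2 libraries, per the file headers. They were copied and not used to call differences.

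Reads were recovered by dividing each value by its step, which gave 7699490 reads for UM-SCC6-M and 8182958 for the parental library. Reads in both libraries were known for 555 miRNAs. The log2 ratio was computed from the scaled values with 0.5 recovered reads added to each library. Its exact interval came from the binomial (Clopper-Pearson) 95% interval of 1 library's share of the reads of that miRNA, converted to a ratio. Shares of a library's reads have Clopper-Pearson intervals too. All intervals cover counting error only.

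With 1 library per group no test between conditions was made. A miRNA was called by a fixed rule of size, a difference of at least 2-fold with at least 50 normalized reads in the higher library, which 179 miRNAs reached. The plan was made before the data were examined and foresaw a trimmed mean of M-values scaling if the table held counts. The table held scaled values, so the authors' scaling was used, and the trimmed mean was computed from the recovered reads as an added alternative. For the lists, the median log2 ratio of members with at least 10 normalized reads was ranked among 10000 random lists, each member being replaced by 1 of the 30 miRNAs nearest in mean abundance. Lists with fewer than 3 such members have no median. For arms, both had at least 50 normalized reads in the higher library. miRNAs read in 1 library only had at least 10 recovered reads there, and their ratio was bounded with 3 reads in the other library. The lists were fixed before the data were examined and overlap in places, for example between the stromal, CD44-targeting and invasion-suppressing lists.

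The miRNAs named were set by rule: miR-218-5p and other products of its hairpins, the 12 highest and 12 lowest log2 ratios among those at 50 or more normalized reads, the 10 most abundant of each library, up to 4 abundant members of each list described and any member at least 2-fold apart, the 5 largest arm differences, and miRNAs read in 1 library only. Others past the size rule, the remaining arm pairs and single members of lists beyond the 4 were named after their values were seen. Names were matched exactly. Hairpin positions and host genes were looked up by name in GENCODE release 29 (GRCh38), and do not come from the authors' file.

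The script was tested on simulated data made from these libraries, with 200 of 555 miRNAs changed 4-fold and only counting (Poisson) error added. Variation between cultures or library preparations was not simulated, so the outcomes of this test do not bear on it. Above the floor it recovered 82 of 82 changed miRNAs, and 0 of 103 unchanged ones passed the rule. The intervals covered the true ratio for 94.1% of miRNAs. Of simulated lists without a shift, 6.25% lay outside the central 95% of their random lists. Alternatives tried were other scalings (total reads, median of ratios, total without the 10 most abundant miRNAs, the deposited fold changes), other floors of 10 and 200 normalized reads or none, thresholds of 1.5-fold and 4-fold, 5 reads added before the log, 1 name per pair of near-identical entries, and intervals wholly beyond 2-fold. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.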

Results

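Small RNAs were sequenced from 2 cultures of the human oral squamous cell carcinoma line UM-SCC6. The first culture was the parental line. The second, UM-SCC6-M, was grown from cells recovered at the invasion front of a microfluidic chip and had passed 3 rounds of that selection. The labels describe it as highly invasive, with mesenchymal features. MicroRNAs (miRNAs) are short RNAs that pair with messenger RNAs and lower their output. Each is cut from a hairpin precursor whose 5p and 3p arms can both give a mature product. Each culture gave 1 library, so no difference below has a replicate check and no test between the conditions was made. The UM-SCC6-M library held 7699490 recovered miRNA reads and the parental library 8182958. Some pairs of names from opposite strands of 1 locus had nearly the same reads, such as miR-7-5p and miR-3529-3p (77230 and 76484 UM-SCC6-M reads). Both names of such pairs enter these sums and the shares and counts below. Values are normalized reads as scaled by the authors, and log2 ratios are UM-SCC6-M over parental. Brackets give exact 95% intervals of the ratio, which cover counting error only, since reads multiplied by PCR are not independent molecules.

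The title of the series names miR-218-5p, and its level in the invasive cells was the first question. miR-218-5p was 6.33-fold lower in the UM-SCC6-M library (interval 5.28 to 7.69), with 16 normalized reads against 101.7 in the parental library. These values rest on 134 and 765 reads, and the log2 ratio was -2.66 (-2.94 to -2.40). Among the miRNAs with at least 50 normalized reads in the higher library, miR-32-5p, miR-29b-3p and miR-7974 had lower ratios. Its 2 hairpins lie in introns of genes for secreted axon guidance ligands. MIR218-1 lies in an intron of SLIT2 on chromosome 4 (20528275 to 20528384, plus strand) and MIR218-2 in an intron of SLIT3 on chromosome 5 (168768146 to 168768255, minus strand) in GRCh38. The mature product is the same for both, so its reads do not tell which locus they came from. No 3p product of either hairpin was among the miRNAs analysed here. In the authors' deposited table miR-218-5p had a log2 fold change of -2.6675 and a q-value of 4.49e-13, a figure that compares these 2 libraries and not the 2 conditions.

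Across the miRNAs with at least 50 normalized reads in the higher library, differences of at least 2-fold were more often toward lower values in the UM-SCC6-M library. Of 179 such miRNAs, 13 were at least 2-fold higher, 23 at least 2-fold lower and 143 within 2-fold. The counting interval lay wholly beyond 2-fold for 11 of the higher and 21 of the lower miRNAs. This balance depended on the scaling. With both libraries scaled to their total reads, 22 were higher and 20 lower, because that scaling moves every log2 ratio up by 0.24.

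**Figure D1:**
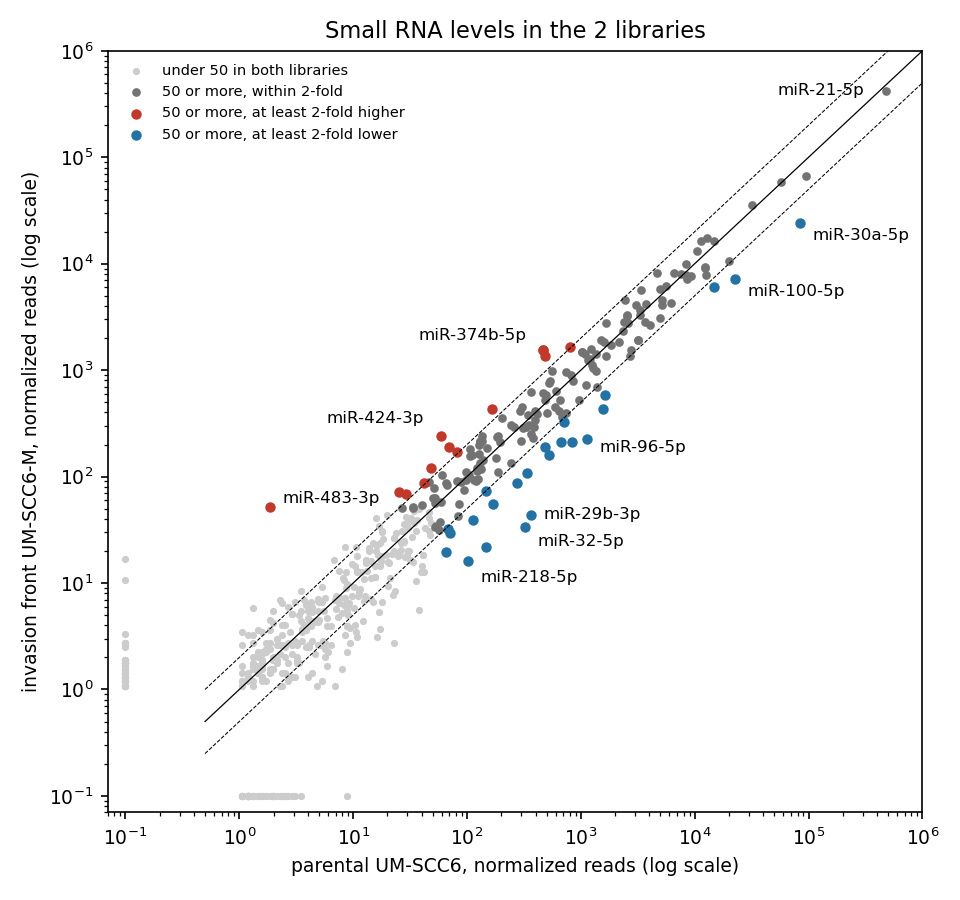
Normalized reads of each miRNA with known reads in both libraries, parental on the horizontal and UM-SCC6-M on the vertical log axis, with 1 point per miRNA. Values listed as 0 are drawn at the lower edge of their axis. The solid line marks equal values and the dashed lines a 2-fold difference, and 13 red and 23 blue points lie on or beyond them at 50 or more normalized reads.

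At 50 or more normalized reads, the largest difference toward the UM-SCC6-M library was that of miR-483-3p, which is encoded in an intron of the growth factor gene IGF2 (chromosome 11, 2134134 to 2134209, minus strand). It was 26.9-fold higher, with an interval of 16.4 to 51.3, on 433 reads against 14. The other arm, miR-483-5p, was 17.1-fold higher on 142 reads against 7, below that floor, and is named after its values were seen. Neighbouring hairpins on chromosome X, between positions 134540185 and 134546711 of the minus strand, also gave higher values. From these, miR-424-3p was 4.08-fold higher (3.68 to 4.53), miR-450a-5p 2.80-fold, miR-450b-5p 2.76-fold, miR-542-3p 2.46-fold and miR-503-5p 2.36-fold. miR-374b-5p was 3.30-fold higher (3.18 to 3.43). miR-374c-3p, from the opposite strand of the same chromosome X locus, had nearly the same read counts, so these 2 names stand for 1 measurement. Both arms of miR-365a were higher, miR-365a-3p by 2.59-fold and miR-365a-5p by 2.07-fold. The others were miR-4521 (2.77-fold), miR-28-3p (2.07-fold), encoded in an intron of the adhesion gene LPP, and miR-199b-5p (2.07-fold).

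Among the miRNAs lower in the UM-SCC6-M library, miR-32-5p was 9.61-fold lower (8.51 to 10.9), on 282 reads against 2440. Its hairpin lies in an intron of TMEM245 on chromosome 9 (109046229 to 109046298). miR-29b-3p, of a family that represses collagen and other matrix transcripts, was 8.33-fold lower (7.48 to 9.33), and miR-7974 was 6.73-fold lower. The far more abundant miR-29a-3p of the same family was 1.61-fold lower, at 3073 against 4939 normalized reads. miR-96-5p was 5.02-fold lower (4.78 to 5.28), at 223.4 against 1122 normalized reads. miR-455-5p, from an intron of the collagen gene COL27A1, was 3.96-fold lower. Of the most abundant miRNAs, miR-30a-5p was 3.50-fold lower (3.48 to 3.52), miR-100-5p 3.21-fold lower (3.18 to 3.24) and miR-148a-3p 2.5-fold lower (2.47 to 2.52). miR-30e-5p was 3.62-fold lower, miR-339-3p 3.33-fold, miR-147b 3.32-fold and miR-21-3p 3.22-fold. The remaining 10 lay between 2.01-fold lower, for miR-140-5p, and 3.14-fold lower, for miR-548o-3p.

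**Figure D2:**
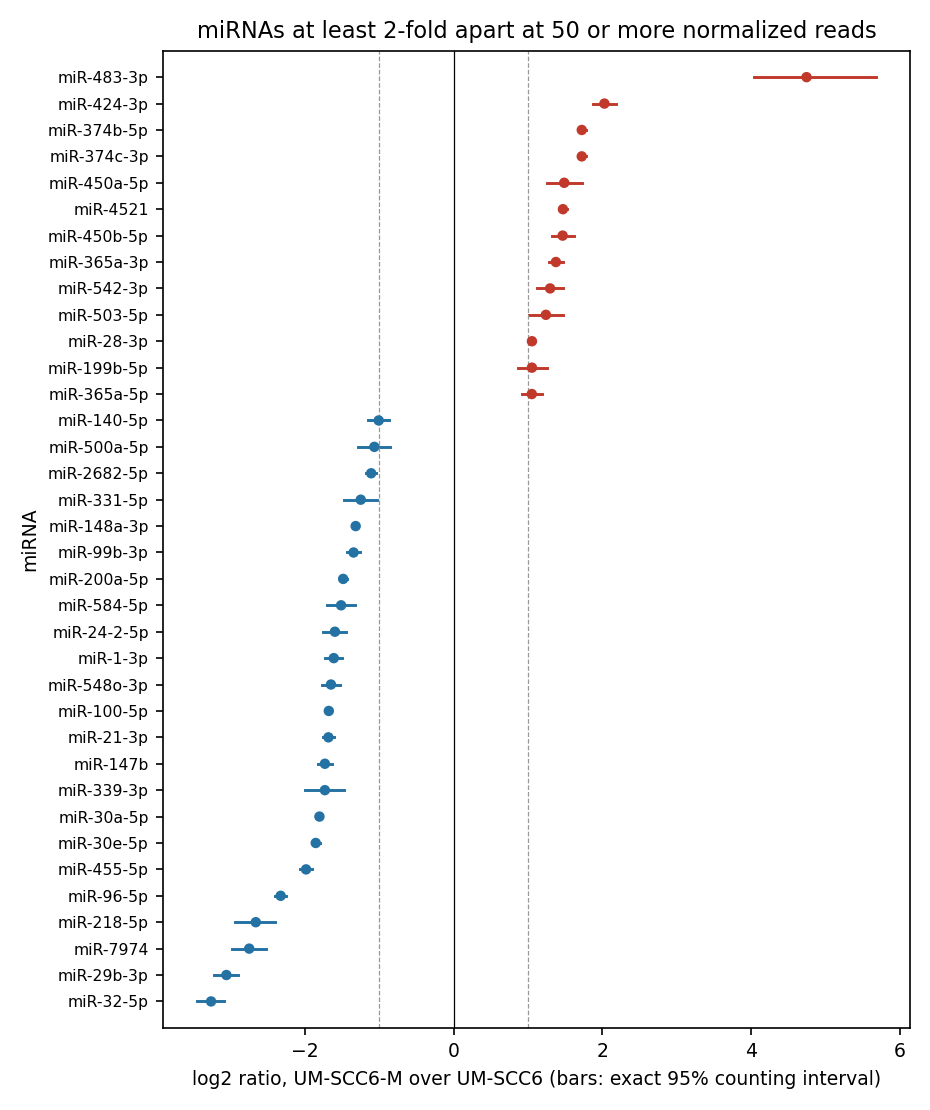
Log2 ratios of the 36 miRNAs at least 2-fold apart at 50 or more normalized reads, with exact 95% counting intervals as bars and the 2-fold bounds as dashed lines. miR-483-3p has the widest interval because only 14 parental reads stand behind it, and miR-218-5p lies at -2.66.

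The next question was which miRNAs made up each library. miR-21-5p, an abundant miRNA of many carcinomas, held 46.0% of the reads in the UM-SCC6-M library (exact interval 45.95 to 46.02) and 43.8% in the parental library (43.75 to 43.82). Its normalized level was 1.13-fold lower in the UM-SCC6-M library under the authors' scaling, and its log2 ratio turned from -0.17 to 0.07 when the libraries were scaled to their totals. Because of this dependence no direction is given for miR-21-5p. miR-30a-5p held 2.61% of the UM-SCC6-M reads (2.60 to 2.62) and 7.72% of the parental reads (7.70 to 7.74). let-7i-5p was second in both libraries, at 7.30% and 8.78%. The 10 most abundant miRNAs together held 74.1% of the UM-SCC6-M reads and 76.3% of the parental reads, and 8 of them were the same. miR-146a-5p and let-7a-5p were in the first 10 only in the UM-SCC6-M library, and miR-100-5p and miR-148a-3p only in the parental library.

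Groups of miRNAs with a shared sequence, locus or reported function were then compared. Of the 27 lists, 17 had at least 3 members with 10 or more normalized reads. The median of each was ranked among those of 10000 random lists of equal size and like abundance, as a description of these 2 libraries. The medians of 2 of these 17 lists lay outside the central 95% of their random lists. Of simulated lists without a shift, 6.25% lay outside, so among 17 lists some can do so without any shift. Cell type markers are given separately below.

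The list of miRNAs reported to suppress invasion or metastasis tended to lower values in the UM-SCC6-M library. The median log2 ratio of its 13 members at 10 or more normalized reads was -0.68, at percentile 0.725 of the random lists. At least 2-fold lower were 5 members, and none was 2-fold higher. These were miR-29b-3p, miR-100-5p, miR-1-3p (3.06-fold lower), miR-138-5p (2.79-fold) and miR-143-3p (2.53-fold, on 34 against 78 reads). Of these 5, miR-1-3p is also in the muscle list, miR-138-5p in the neural list and miR-143-3p in the stromal list below. miR-26a-5p (log2 ratio 0.26), miR-26b-5p (0.45), miR-146a-5p (0.31) and miR-99a-5p (0.53) lay above 0. With the 11 members at 50 or more normalized reads the median was -0.46, at percentile 3.33, which is inside the central range. The list of miRNAs reported to promote invasion had a median of -0.07 over 11 members, none of them 2-fold apart, and that median turned to 0.17 under scaling to the totals. miR-222-3p was its lowest member at -0.54 and miR-155-5p its highest at 0.24.

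The let-7 family, whose members repress RAS and HMGA2 transcripts, had a median log2 ratio of 0.37 over 9 members, at percentile 98.5. let-7b-5p was highest at 0.93, followed by let-7c-5p at 0.78, let-7d-5p at 0.56 and let-7a-5p at 0.52. No member was 2-fold apart. The most abundant member, let-7i-5p, went the other way at -0.51, and the summed level of the family had a log2 ratio of -0.11, which turned to 0.13 under scaling to the totals. The sum therefore gave no direction. Members differ from each other by few bases, so reads can be assigned to more than 1 of them.

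miRNAs of the epithelial state did not move together. miR-200b-3p, the most abundant of the miR-200 family, which represses ZEB1 and ZEB2, had 17481 against 12823 normalized reads and a log2 ratio of 0.45. miR-200a-3p, from a hairpin less than 1 kb away on chromosome 1, was 1.99-fold lower, and miR-429 had a ratio of -0.09. The other arms of these hairpins are in no list. miR-200a-5p was 2.80-fold lower (2.71 to 2.90) and passed the size rule, whereas miR-200b-5p had a log2 ratio of 0.79. miR-200c-3p had 15 reads in the UM-SCC6-M library and 20 in the parental library, too few to show a difference. miR-141-3p and miR-205-5p had no entry under these names among those deposited, so nothing can be said of them. The family median was -0.09 under the authors' scaling and 0.15 under scaling to the totals, so it gave no direction. Of the squamous and keratinocyte miRNAs none of 5 was 2-fold apart, with miR-24-3p at -0.71 and miR-23b-3p at 0.34.

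**Figure D3:**
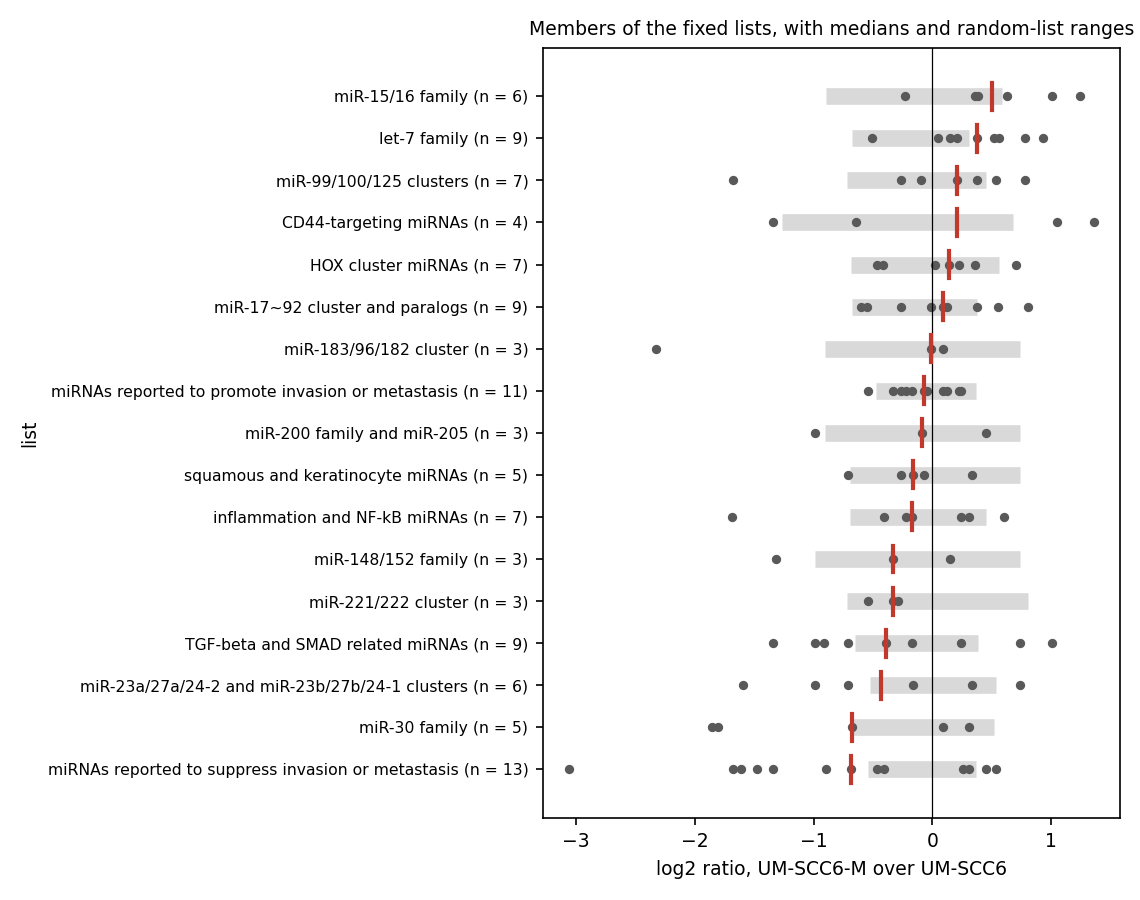
Log2 ratios of the members of each list with 3 or more members at 10 or more normalized reads, as points, with the list median as a red bar and the central 95% of medians of random lists as a grey band. The medians of the let-7 family at 0.37 and of the miRNAs reported to suppress invasion at -0.68 lie outside their bands.

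Several families held members that lay far apart. In the miR-30 family, which is reported to repress SNAI1, miR-30a-5p and miR-30e-5p were at -1.81 and -1.86, whereas miR-30c-5p was at 0.31 and miR-30b-5p at 0.09. The family median was -0.68, at percentile 3.69. In the miR-15 and miR-16 family, miR-503-5p and miR-424-5p were 2.36-fold and 2.01-fold higher, and the median was 0.50 at percentile 94.8. In the 2 clusters of miR-23, miR-27 and miR-24, miR-23a-3p was at 0.74, miR-27a-3p at -0.99 and miR-24-2-5p at -1.60, with a median of -0.44 at percentile 4.42. Without the floor that median was -0.71, at percentile 0.605, outside the central range. In the cluster of miR-183, miR-96 and miR-182 only miR-96-5p was 2-fold apart, with miR-183-5p at -0.01 and miR-182-5p at 0.09, values near 0 whose sign for miR-183-5p changes with the scaling. In the clusters of miR-99, miR-100 and miR-125, miR-100-5p stood at -1.68 and miR-99a-5p at 0.53. In the family of miR-148 and miR-152, miR-148a-3p was at -1.32 and miR-148b-3p at 0.15.

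Of the CD44-targeting miRNAs, 4 reached 10 normalized reads. miR-328-3p was 2.56-fold higher (2.08 to 3.19) and miR-199a-3p 2.07-fold higher, while miR-143-3p was 2.53-fold lower and miR-34a-5p 1.56-fold lower. CD44 is the hyaluronan receptor that the series title also names. The median of 0.21 therefore describes members that went both ways. It turned to -0.64 without a floor and with the deposited fold changes, and stayed at 0.21 without a floor on recovered reads. The hypoxia-induced miR-210-3p had a log2 ratio of 0.13, with an interval of -0.07 to 0.32.

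The medians of the other lists, cell type markers aside, lay inside their random ranges at this floor. Medians were 0.09 for the miR-17~92 cluster and its paralogs, 0.14 for the HOX cluster miRNAs, -0.34 for the cluster of miR-221 and miR-222, -0.17 for the inflammation miRNAs (0.07 under scaling to the totals) and -0.39 for the TGF-beta related miRNAs. The last of these was -0.71, at percentile 1.19 and outside the central range, without a floor and with the deposited fold changes, and -0.55 at percentile 3.9 without a floor on recovered reads. miR-92a-3p was the highest of the miR-17~92 list at 0.80. The group of miR-192, miR-194 and miR-215, the miR-29 family and the chromosome 19 cluster had 2 members each at 10 or more normalized reads, and the family of miR-34 and miR-449 had 1. No member reached that floor from the DLK1-DIO3 cluster or from those of miR-371 to miR-373, miR-506 to miR-514 and miR-224 with miR-452. Below the floor, the 7 DLK1-DIO3 members whose reads were known in both libraries had a median log2 ratio of 1.1, at percentile 98.2, and went both ways. Reads were known only where at least 1 library had a listed value. miR-889-3p, miR-409-3p, miR-323a-3p and miR-654-3p were listed at 0 in the parental library and entered through their UM-SCC6-M value, so this median depends in part on that filter. The 15 members with a deposited fold change had a median of 1.17, at percentile 99.6. miR-889-3p had 16 reads against 5, miR-409-3p 15 against 6, miR-323a-3p 13 against 4 and miR-654-3p 12 against 4, whereas miR-381-3p had 13 against 60, miR-379-5p 30 against 29 and miR-411-5p 7 against 8. The counting intervals of all but miR-889-3p and miR-381-3p included a log2 ratio of 0.

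Markers of other cell types differed by list. Of the fibroblast or stromal miRNAs, 3 reached 10 normalized reads, with a median of 1.05 at percentile 98.5, outside the central 95% of random lists. miR-199b-5p and miR-199a-3p were both 2.07-fold higher and miR-143-3p was 2.53-fold lower, and miR-145-5p, miR-214-3p and miR-127-3p were listed at 0 in both libraries. The median is the value of miR-199b-5p. miR-199b-3p had no entry under that name, and whether reads named miR-199a-3p came from the miR-199b hairpin was not tested. The higher values of miR-199b-5p and miR-199a-3p may therefore not be independent. Below the floor the stromal markers also went both ways. miR-199a-5p had 1 read against 13, and miR-409-3p had 15 against 6, the latter within counting error. The arms of the endothelial miR-126 hairpin differed, with miR-126-3p at -0.90 and miR-126-5p at 0.78. Of the blood cell miRNAs, miR-486-5p stood at 17.9 against 24.6 normalized reads, while miR-142-3p and miR-451a were listed at 0. The muscle miRNAs whose reads were known in both libraries all had lower values in the UM-SCC6-M library. miR-1-3p was 3.06-fold lower, and below the floor miR-499a-5p had 33 reads against 67 and miR-133a-3p had 21 against 31, the latter within counting error. The liver miRNA miR-122-5p had 2 reads against 15. The neural list had a median of -0.26 over 4 members, with miR-138-5p at -1.48, miR-128-3p at -0.29, miR-9-5p at -0.23 and miR-129-5p at 0.08. The epithelial markers at 10 or more normalized reads were the 3 of the miR-200 list.

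The arms of single hairpins were compared next. Of 30 hairpins with at least 50 normalized reads for both arms, 9 differed between the libraries by 1 or more in the log2 ratio of the 5p to the 3p arm. The largest counting standard error of any of these differences was 0.14. miR-30a-5p was at -1.81 while miR-30a-3p was at 0.16, and miR-30e-5p was at -1.86 while miR-30e-3p was at 0.07. The balance of miR-455 and miR-181a also lay more toward the 3p arm in the UM-SCC6-M library, by 1.66 and 1.47. It lay more toward the 5p arm for miR-339 (1.80), miR-21 (1.51), miR-151a (1.46), miR-374b (1.29) and miR-99b (1.25). For miR-21 this came from the minor arm, as miR-21-3p was 3.22-fold lower. Arm differences do not depend on the scaling. miR-423 and miR-3184 lie on opposite strands of 1 locus and share their reads, so these 2 of the 30 hairpins stand for 1 measurement.

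**Figure D4:**
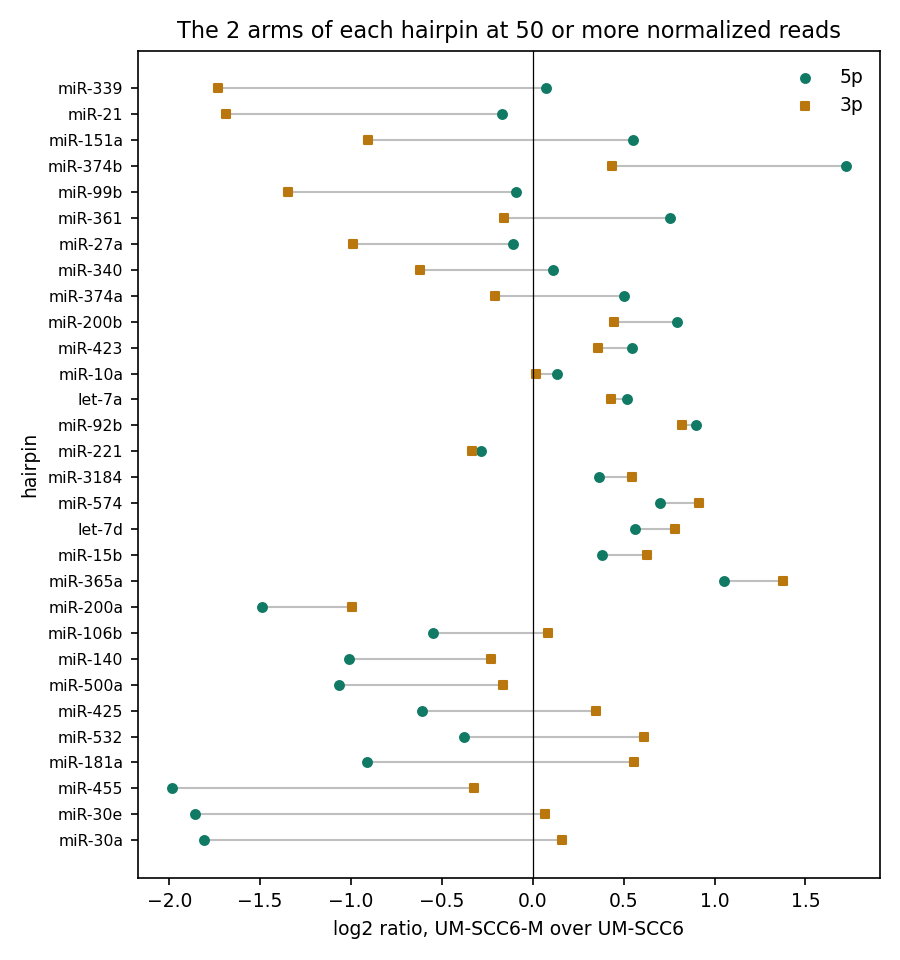
Log2 ratios of the 5p arm (circles) and the 3p arm (squares) of the 30 hairpins, joined by a line for each hairpin and ordered by their difference. The lines are longest for miR-30a, miR-30e and miR-339, whose arms differ by -1.97, -1.92 and 1.80.

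miRNAs with no reads in 1 library and at least 10 in the other were few and of low count. miR-100-3p had 12 reads and miR-4522 had 10 reads in the parental library and none in the UM-SCC6-M library. Against a floor of 3 reads per library they were at least 4.45-fold and 3.71-fold lower in the UM-SCC6-M library. miR-450a-2-3p had 11 reads in the UM-SCC6-M library and none in the parental library, 3.29-fold higher on the same basis.

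In the authors' deposited table, 150 miRNAs had a q-value under 0.05, and 51 of these were also at least 2-fold apart, 19 higher and 32 lower in UM-SCC6-M. The authors marked 44, of which 17 were higher and 27 lower, and every marked miRNA had a q-value of at most 0.0083. Among the marked, 35 also passed the size rule used above and 9 had under 50 normalized reads in both libraries. These q-values compare 1 library with 1 library.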

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

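Choices fixed before the data were examined were changed 1 at a time, except that the alternatives without a filter also took the deposited fold changes, which cover miRNAs listed at 0. The trimmed mean scaling, the floor of 50 recovered reads and the alternatives without a filter on recovered reads were chosen after seeing the data. No paired analysis was possible because each group has 1 library. The miR-218-5p log2 ratio lay between -2.67 and -2.42 under all 6 alternatives tried, of which the deposited fold change has the scaling of the main value. The counts of 13 higher and 23 lower miRNAs moved by more than 1.5 times as follows. Scaling to total reads gave 22 higher, with 20 lower, since it moves every log2 ratio by 0.24. A floor of 10 normalized reads gave 21 and 45, a floor of 200 gave 6 and 15, and no filter gave 115 and 188 with the deposited fold changes and 59 and 110 with recovered reads. A floor of 50 recovered reads gave 26 and 54. A threshold of 1.5-fold gave 32 and 46, and 4-fold gave 2 and 5. These floors and thresholds change how many miRNAs can be counted, by construction. The other scalings moved log2 ratios by 0.02 to 0.07 and gave 13 higher and 21 to 22 lower.

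The number of lists outside their random range, 2, became 1 with members at 50 or more normalized reads, where 16 lists could be ranked. Without a filter it became 6 of 22 lists with the deposited fold changes and 4 of 21 with recovered reads, and the cause was not tested. Those added were the DLK1-DIO3 cluster and the clusters of miR-23, miR-27 and miR-24 in both, and the TGF-beta list and the family of miR-34 and miR-449 with the deposited fold changes. A change of scaling moves members and random lists alike, so it cannot change the number outside. Without miR-21-5p the other 9 most abundant miRNAs held 52.1% of the UM-SCC6-M reads and 57.9% of the parental reads. At a floor of 200 normalized reads 5 hairpins differed by 1 or more between arms, in place of 9. With at least 50 reads required, 0 miRNAs were read in 1 library only. Of 198 values for 33 other named miRNAs, 127 stayed inside their counting interval and 71 moved out of it. The deposited fold changes have the scaling of the main values, so those values stayed inside by construction. Each other scaling moves all log2 ratios alike, so a value moves out where its interval is narrow. This tally is therefore no measure of how firm the differences are. Among these 33 the only change of sign was that of miR-21-5p, to 0.07 under total reads. Other miRNAs near 0 that are not among them, such as miR-183-5p and miR-429, also changed sign under total reads. Over the alternatives for 17 list medians, 13 values in 6 lists changed sign, all in lists inside their random range. Depth limits miRNAs with few reads, and no depth replaces the missing replicates.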

Other observations

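All tests in this part were chosen after the data had been seen. The products of 1 chromosome X locus, most of them in no list, stood together. The 6 miRNAs from the miR-424, miR-503, miR-542 and miR-450 hairpins with at least 10 normalized reads were all higher in the UM-SCC6-M library, with log2 ratios from 1.009 for miR-424-5p to 2.03 for miR-424-3p and a median of 1.38. miR-450a-2-3p, from the same locus, had 11 reads there and none in the parental library. These hairpins lie within 10 kb of each other.

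For this locus a higher level of chromosome X miRNAs as a whole was tested on 24 other miRNAs with a single locus on that chromosome, whose median log2 ratio was -0.14 (bootstrap interval -0.29 to 0.37), far from the 1.38 of the locus. A common scaling factor moves both medians alike and leaves the gap between them as it is. A difference between the 2 library preparations cannot be told apart from the selection of invasive cells, because there was 1 library per group. A shared change in transcription or dosage of this locus in the selected cells may be the source, as a hypothesis that these data leave untested.

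Arms of the same hairpin lay 1.25 to 1.97 apart for 9 hairpins. Base composition as a cause was examined with the GC of the 5p and 3p sides of the hairpin precursor, not of the mature miRNAs. The arm difference was correlated with the GC difference of the sides over 29 hairpins, which are not independent replicates. Pearson r was -0.048 (bootstrap interval -0.33 to 0.25) and Spearman rho -0.11, so no linear trend with this measure was seen. Among the 9 hairpins the GC difference only ranged from -8.33 percentage points for miR-21 to 8.33 for miR-455. With this narrow range, and without the GC of the mature miRNAs, the test cannot decide, and base composition stays open. Reads of miR-30a-5p moved to the near-identical miR-30d-5p and miR-30e-5p were tested by the sum of the 3, whose log2 ratio of -1.60 (-1.61 to -1.60) argues against it. For reads of miR-30e-5p moved to the other 2 this stays open, since its difference was 1.75% of theirs and would not show in the sum. A difference between the 2 library preparations, such as in ligation or size selection, cannot be told apart from a difference in the cells with 1 library per group. Differences in arm choice or in the stability of single mature miRNAs may also account for it and remain untested.

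The deposited p-values were very small for some miRNAs with a fold change near 1, for example 2.52e-214 for miR-21-5p, whose deposited log2 fold change was -0.17. A test centred on the ratio of the 2 column totals, a normal approximation for 2 samples of reads, gave the authors' p-values within 1% on the log10 scale for 100% of the miRNAs above 0 in both libraries with a p-value above 0 and under 0.9. A test centred on equal normalized values gave 0%. The centre would then lie at a log2 fold change of -0.24, and so 6 miRNAs with a q-value under 0.05, miR-21-5p among them, have a deposited fold change whose sign is opposite to the direction that was tested. The deposited q-values may therefore not follow the deposited fold changes near 1, while miR-218-5p lies far from either centre.

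Shared transcription of neighbouring hairpins was examined as a hypothesis. Over 67 pairs of miRNAs from different hairpins on the same strand within 10 kb, the median absolute difference of log2 ratios was 0.54, against 0.78 for shuffled miRNAs, at percentile 3.05 of 10000 shuffles. Without the miR-424 to miR-450 hairpins it was at percentile 3.97. This leans toward neighbours being alike but did not pass the 2.5 percentile set for it, and pairs such as miR-96-5p and miR-183-5p, at -2.33 and -0.01, lay far apart.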
